A study of Homo sapiens with 2 samples.

How the data were processed

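Messenger RNA levels were measured on 2 oligonucleotide microarrays labelled as MCF7, an established human breast cancer cell line of luminal, oestrogen receptor-positive type. Per the labels, one array carried RNA of cells transfected with an empty control vector and the other RNA of cells transfected with a vector for the 6SA mutant of Snail, the transcriptional repressor encoded by SNAI1. In this mutant, serines that are phosphorylated on the way to degradation are replaced by alanine, which stabilises the protein. Total RNA was turned into biotin-labelled cRNA and hybridised to Affymetrix Human U133 Plus 2 arrays at a core facility, per the labels' protocols. These are 1-colour arrays that measure each transcript by 1 or more sets of short probes near its 3' end.

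The deposited values are linear intensities, 1 per probe set and array. The scaling follows from the values: the mean intensity over all probe sets, leaving out the highest 2% and the lowest 2%, was 500.1 on both deposited arrays, so the authors had scaled each array to a common trimmed mean. The software, the background correction and any detection calls are not given in the sources used here. The authors' own pathway analysis drew on Reactome gene sets, per the labels, and was not repeated here. Replicates were not analysed here: each group is 1 array. No test between the groups is therefore possible and no p-value is given. With 1 array per group, the spread between cultures is unknown. Brightness is a further limit, since a gene below background on 1 array gives only a bound.

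Of 54675 probe sets, 62 are control probe sets. Probe sets were named through the platform annotation given with the data. There, 41097 probe sets had exactly 1 gene symbol, 1801 had several and 11777 had none. Gene identifiers of 41043 of the probe sets with 1 symbol matched the RefSeq gene table of assembly GRCh38.p14, and 0 of them needed a newer symbol. Probe sets with several symbols or none were not used for named genes. Genome positions are not given, because the sources used here name no genome build for the probes.

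The rule fixed before the data were examined called for quantile normalisation if the arrays' medians or 75th percentiles differed by more than 0.1 on the log2 scale. The deposited arrays differed by 0.18 in the median and by 0.20 in the 75th percentile, so log2 intensities were quantile normalised. Background was set per array at the 90th percentile of 215 probe sets of olfactory receptor, bitter taste receptor, keratin-associated protein, defensin and gamma-crystallin genes, which a breast cell line is not known to use. It was 6.85 log2 units on the control vector array and 6.48 on the array labelled 6SA-Snail. Values below background were raised to it, so a difference of a gene that is above background on 1 array is a lower bound, written "at least". A bound pointing away from the array on which the gene was seen was set to 0, a rule added after the data had been seen. Each gene was represented by its brightest probe set over both arrays. Unless stated, linear intensities of single genes are given as deposited, while folds and log2 values are those after normalisation.

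Of 19775 genes with a probe set, 13389 were above background on at least 1 array and 10635 on both. A gene is said to have risen or fallen when its log2 difference, 6SA-Snail minus control vector, was at least 1 (2-fold) and all its probe sets above background that gave a direction moved the same way. The disagreement between the 2 brightest probe sets of 5029 genes gave a robust SD of 0.46 log2 units for 1 probe set. This covers probe design and scanning only.

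26 gene lists were fixed before the data were examined. For each, the median difference of its members above background was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart when its median lay below the 2.5th or above the 97.5th percentile, which describes these 2 arrays and is not a test of the treatment. Named genes were also chosen by a rule fixed in advance. They are SNAI1, the 12 largest rises and 12 largest falls among genes above background on both arrays, the 5 largest bounds each way, up to 4 members of each list with the largest differences, and 13 fixed genes (CDH1, VIM, FN1, CDH2, ZEB1, SNAI2, TWIST1, ESR1, GATA3, CD44, MKI67, GAPDH and ACTB). Genes known only by a locus or clone number, XIST and Y-linked genes were passed over. Other genes are named where a count was 5 or fewer, and these were chosen after their values were seen. Lists of cell line markers, and 28 gene families, were chosen after a first look at the data.

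The procedure was tested on simulated data made from the control vector array with noise of 0.3 log2 units, in which 200 of 12258 genes were changed. The changed genes were drawn only from genes well above background. This noise is below the 0.46 found for 1 probe set and holds no spread between cultures. Far fewer genes were changed than the 35.9% that differed between the real arrays. The simulation checks the procedure and gives no error rate for these arrays. Changes of 1.5 log2 units up or down were recovered in 96% of genes, larger ones in 100%, and 9 of 12058 unchanged genes were called. Of 600 random lists of 25 genes, 5.17% fell outside the limits (the number of lists was raised from 200 after a first run had given a lower share), and 96% of lists shifted by 1 log2 unit were found. The list check shuffled the measured differences among genes, so the share outside the limits follows from the limits themselves. Alternatives tried were the values as deposited, median centring, the mean of all probe sets, leaving out probe sets that can bind several transcripts, other backgrounds, a pseudocount of 32, other fold thresholds, no need for probe sets to move the same way, random lists not matched on expression, and members above background on both arrays only. One more, a background common to both arrays, was added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.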

Results

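Transcript levels on an array labelled as MCF7 breast cancer cells with a control vector were compared with those on an array labelled as MCF7 with 6SA-Snail, with 1 array per group. Per the labels, the comparison addresses which genes and pathways differ when a stabilised Snail is introduced. The values put this reading in doubt. SNAI1 was not above background on either array, and the origin of the cells labelled 6SA-Snail is in question, as described below. No difference below can be assigned to Snail. Deposited intensities ran from 0.3 to 101193 on the control vector array, with a median of 91.4, and from 0.2 to 79609 on the array labelled 6SA-Snail, with a median of 103.6. Above background were 11860 genes on the former and 12164 on the latter. No value below has a replicate, and no difference could be set against a spread between cultures.

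SNAI1, the gene introduced, was not above background on either array. Its probe set read 78.8 on the control vector array and 18.2 on the array labelled 6SA-Snail as deposited. After normalisation it read 6.38 and 4.12 log2 units, against background levels of 6.85 and 6.48 (115.6 and 89.5 in linear units). The array therefore gave no sign of raised SNAI1 RNA in the cells labelled 6SA-Snail. Whether the transfected construct carries the 3' part that this probe set reads is not given in the sources used here. Because of this, the second array is called the array labelled 6SA-Snail throughout.

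The arrays differed widely. Of 13389 genes above background on at least 1 array, 2144 rose and 2664 fell by at least 2-fold on the array labelled 6SA-Snail, 35.9% together. Which direction had more genes depended on the scaling, with 2397 higher and 2307 lower as deposited and 2436 and 2262 with centring. The largest falls among genes seen on both arrays were those of CD24, a luminal surface glycoprotein, at 169-fold in the brightest of 6 probe sets, all lower, FXYD3, a regulator of the sodium pump, at 159-fold, and DKK1, a secreted Wnt antagonist, at 147-fold. KRT8 (a simple epithelial keratin), ERBB3 (a receptor tyrosine kinase), CRABP2 (a retinoic acid carrier), TNFRSF12A, SYTL5, SFN (14-3-3 sigma), MLPH, NQO1 and TFAP2C fell by between 89.9-fold for KRT8 and 53.5-fold for TFAP2C. The readings of FXYD3, DKK1, ERBB3, TNFRSF12A and SYTL5 on the array labelled 6SA-Snail, 6.58 to 6.78 log2 units, lay near the background of 6.48. Their folds are therefore close to bounds. The other FXYD3 probe set differed by -3.99 on the log2 scale. Genes lost to background included KRT19, another simple epithelial keratin, which was at least 648-fold lower, and TFF1, a classical oestrogen-induced secreted peptide, which was at least 646-fold lower. HSPB1, a small heat shock protein, was at least 630-fold lower, SERPINA3 at least 379-fold lower and the long non-coding RNA DSCAM-AS1 at least 365-fold lower.

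Among genes above background on both arrays, the largest rise was that of LDHB, the heart-type lactate dehydrogenase subunit, at 348-fold in its brightest probe set, with both probe sets higher. HEY1, a Notch target, rose 109-fold, the zinc finger gene ZNF711 101-fold, and CDKN2A, the locus of the cell cycle inhibitor p16, 51.8-fold. The control reading of CDKN2A, 6.94 log2 units, was barely above the background of 6.85, so this fold is close to a bound. Its lowest difference under any alternative was 2.53 on the log2 scale. By textbook knowledge MCF7 cells have lost both copies of CDKN2A. VIM, the mesenchymal intermediate filament vimentin, rose 40.8-fold in its brightest probe set, while its other probe set gave no direction. DLX2, KLHL15, UCHL1, SLIT2, CSRP2, PMAIP1 and CENPV rose by between 39.2-fold for DLX2 and 25.7-fold for CENPV. The control reading of SLIT2, 6.93 log2 units, was also barely above background. IRS4, an insulin receptor substrate, went from 41.9, below background, to 34055 as deposited, a bound of at least 318-fold after normalisation. GPX1, a glutathione peroxidase, was at least 98.1-fold higher, GSTP1, a glutathione transferase, at least 91.7-fold, TMEM47 at least 90.2-fold and the cyclin CCND2 at least 60.6-fold. By contrast, GAPDH differed by -0.06 and ACTB by -0.74 on the log2 scale (-0.36 and -1.03 with values as deposited), and none of 24 ribosomal protein genes passed the 2-fold rule. A dimmer probe set of RPS28 was higher by 2.78 on the log2 scale.

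**Figure D1:**
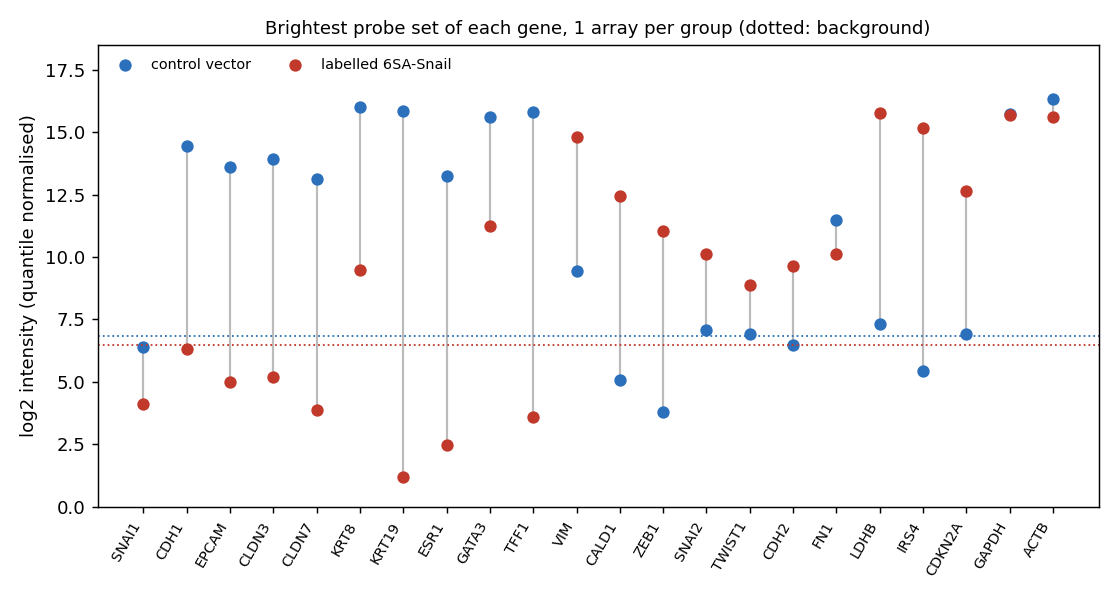
Quantile-normalised log2 intensity (vertical axis) of the brightest probe set of 22 genes on the control vector array (blue) and the array labelled 6SA-Snail (red), 1 array each, with dotted lines at each array's background. SNAI1 lies below background on both arrays, epithelial and oestrogen-related genes are lower on the array labelled 6SA-Snail, and LDHB, IRS4 and CDKN2A are higher there.

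**Figure D2:**
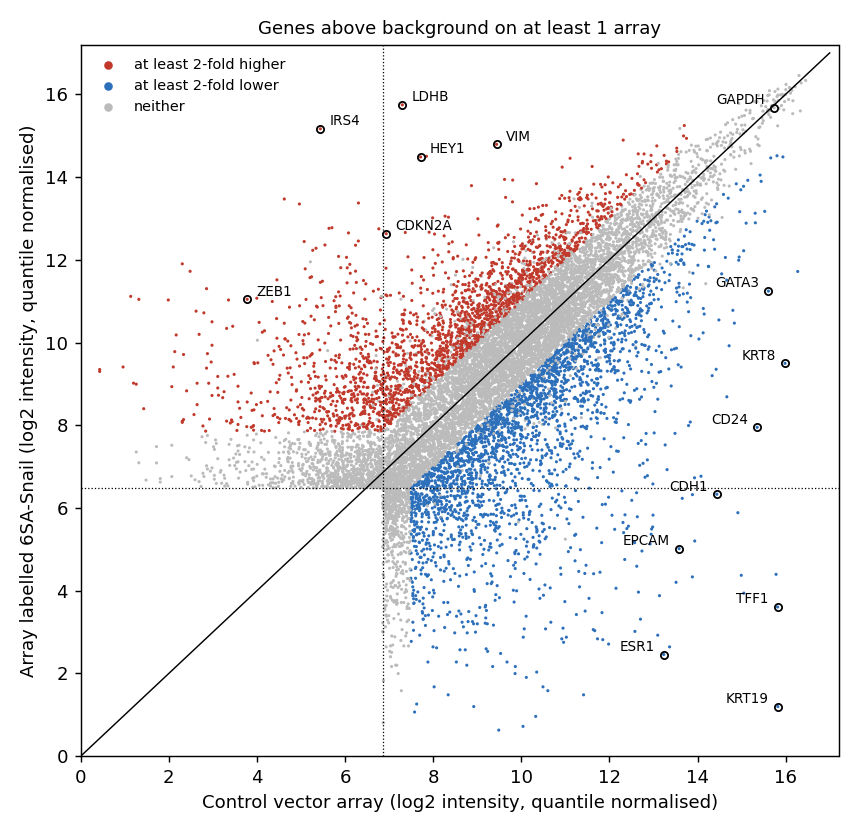
Log2 intensity of 13389 genes above background on at least 1 array, control vector on the horizontal and labelled 6SA-Snail on the vertical axis, with XIST and Y-linked genes not drawn, the line of equality and dotted background levels. Of these genes 2144 rose (red) and 2664 fell (blue) by at least 2-fold, and GAPDH lies on the line.

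Genes of epithelial junctions and cell polarity were lower as a group. Of 36 such genes above background, 25 fell, 4 rose and 7 passed neither rule, and the median log2 difference was -3.57, below all 10000 random lists. CDH1, the E-cadherin gene and a classical target of Snail, went from 23794 to 85.2 as deposited, with both probe sets lower. After normalisation this was a fall of at least 248-fold. The tight junction genes CLDN3 and CLDN7 were at least 175-fold and at least 101-fold lower, and the adhesion gene EPCAM at least 137-fold lower. The 4 that rose were DSC2, DSG2, PKP2 and PKP3, named after their values were seen. They rose 4.95-fold, 4.74-fold, 3.71-fold and 2.96-fold. All encode desmosome components, as do JUP, which fell by 4.06 on the log2 scale, and DSP, which read -0.83, both also named after their values were seen. OCLN, the gene of the tight junction protein occludin and also named after its value was seen, differed by -0.54 in its brightest probe set. All 4 of its probe sets were lower, by between -2.35 and -0.40 on the log2 scale. On the array with these falls, CDKN2A was higher by 5.69 and IRS4 by at least 8.31 on the log2 scale.

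Of 20 genes reported elsewhere as repressed by Snail, 13 fell, 1 rose and 6 passed neither rule, with a median of -3.14, below all 10000 random lists. 15 of the 24 genes listed are also in other lists, so this count is not separate from those. ESR1, the oestrogen receptor alpha gene, fell by at least 108-fold with all 6 probe sets lower, and read -1.12 on the log2 scale with the mean of all probe sets. The gene that rose was CCND2, a cyclin, at least 60.6-fold. Of its 4 probe sets above background 2 were higher and the others gave no direction. Its lowest value under any alternative was 1.82 on the log2 scale. These falls occurred on the array whose SNAI1 probe set was not above background.

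Mesenchymal genes were divided. Of 33 above background, 14 rose, 5 fell and 14 passed neither rule, and the median log2 difference was 0.07, at percentile 92.0 of the random lists. CALD1, encoding the actin-binding protein caldesmon, rose at least 48.1-fold in its brightest probe set, with all 9 higher but the others by bounds of 0.17 to 2.80 on the log2 scale, and LEF1, a Wnt-responsive transcription factor, at least 20.3-fold. The transcription factor gene ZEB1 was at least 18.3-fold higher, SNAI2 8.15-fold and TWIST1 3.83-fold higher, and CDH2, encoding N-cadherin, at least 6.87-fold. The other CDH2 probe set was at least 4.95 higher on the log2 scale. On the array labelled 6SA-Snail it read 3437, against 828.5 for the probe set used. FN1, encoding fibronectin, fell 2.57-fold, with 4 of 4 probe sets lower. With the mean of all probe sets LEF1 read 0.79 and FN1 -0.92, both short of 2-fold. The other members that fell, named after their values were seen, were LOXL2, TPM1, MMP9 and CCN1, by -2.25, -2.14, -1.65 and -1.10 on the log2 scale. IRS4 and CDKN2A were higher on the same array as the rises. The list's place depended on the setting: its median was 0.77 and stood above the random lists with the mean of all probe sets, and was -0.06 over members above background on both arrays.

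Collagens and matrix genes did not stand apart, with 4 of 22 higher, 9 lower and a median of -0.63 at percentile 5.47. Within them COL4A2, a basement membrane collagen, was at least 18.2-fold higher. COL4A1, NID1 and COL6A1, named after their values were seen, were at least 3.66, at least 1.93 and 1.27 higher on the log2 scale, while COL12A1 and TGFBI were at least 24.4-fold and at least 23.3-fold lower and COL5A1 was 16.7-fold lower. The TGF-beta response list stood lower, with 12 of 20 fallen, 0 risen and a median of -2.07, below all 10000 random lists. Its largest falls after TGFBI were those of PMEPA1, a feedback regulator, at 22.1-fold, BMP7 at 12.3-fold and TGFB1 at 11.8-fold. All 4 probe sets of BMP7 were lower, but by as little as -1.08 on the log2 scale. The other probe set of TGFB1 gave no direction, and without probe sets that can bind several transcripts its difference was 0.

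Luminal breast identity genes showed the lowest median of the 26 lists. Of 21 above background, 18 fell and 1 rose, with a median of -4.37, below all 10000 random lists. GATA3, a luminal transcription factor, fell 20.6-fold, with 3 of 3 probe sets lower, but stayed above background at 2369. KRT19, CD24, ESR1 and KRT8 had the largest falls. The gene that rose was TFAP2A, at 6.07-fold, named after its value was seen. Oestrogen response genes were lower too, with 24 of 30 fallen and 0 risen and a median of -3.01, below all 10000 random lists. IGFBP4, GREB1 and EGR3 were at least 74.7-fold, 70.4-fold and 27.0-fold lower. The other GREB1 probe set above background had a bound of -0.55 on the log2 scale, and the smallest fall of GREB1 under any alternative was -1.82. Of the HEK293 list described last, 9 of 15 genes rose on the same array.

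Basal and stem-like markers also stood lower, with 8 of 13 fallen, 1 risen and a median of -1.43 at percentile 0.19. ITGB4, an integrin of hemidesmosomes, was at least 50.8-fold lower, KLF4 fell 8.07-fold, NT5E at least 7.11-fold and ALDH1A3 5.34-fold. The ITGB4 probe sets above background gave bounds from -5.67 to -1.85 on the log2 scale, and its smallest fall under any alternative was -1.70. The gene that rose, LGR5, read at least 2.20 on the log2 scale and was named after its value was seen. CD44, a marker of the basal and mesenchymal state, fell 2.07-fold with 7 of 7 probe sets lower, but read -0.82 as deposited and fell short of 2-fold. Without probe sets that can bind several transcripts the median was -0.81 and the list no longer stood apart.

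**Figure D3:**
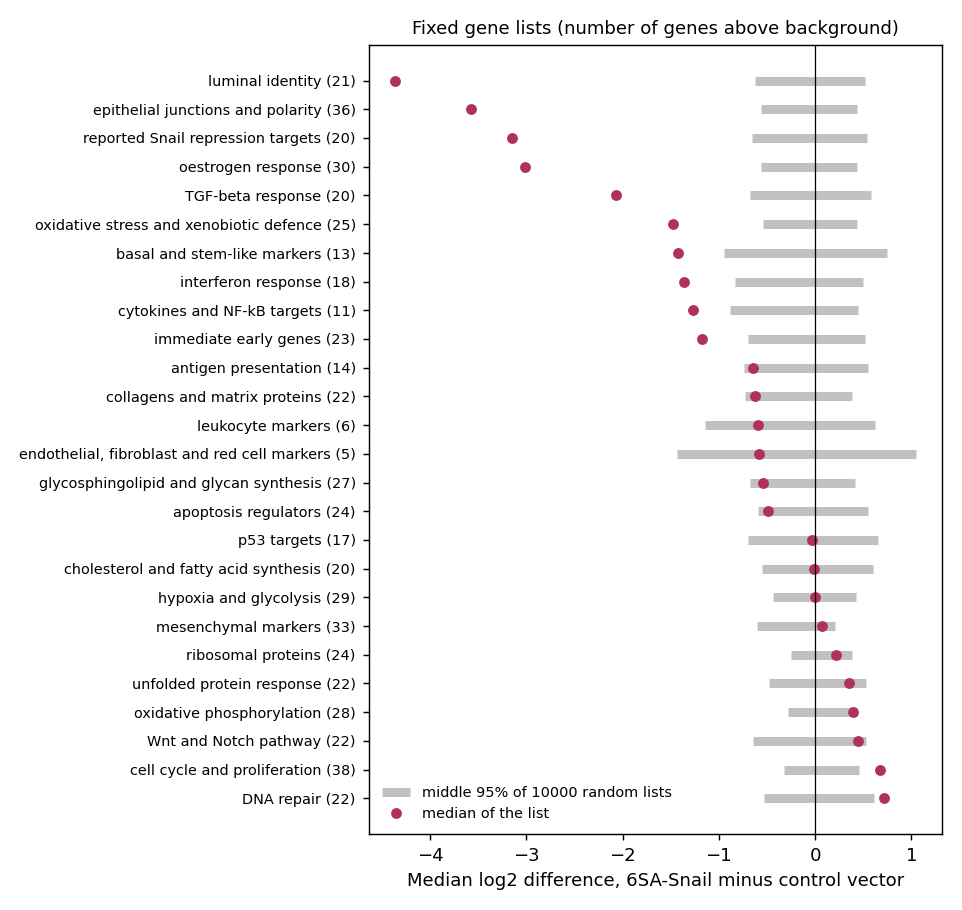
Median log2 difference, 6SA-Snail minus control vector, of each of 26 fixed gene lists (points), with the number of members above background, against the middle 95% of medians of 10000 random lists matched on expression (grey bars). Medians lay below the grey bar for 10 lists and above it for 2, cell cycle and DNA repair.

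Cell cycle genes stood higher. Of 38, 13 rose, 0 fell and 25 passed neither rule, with a median of 0.67 at percentile 99.9. CENPF, a kinetochore protein gene, rose 7.60-fold, CDK1, the mitotic kinase gene, 5.15-fold, KIF11 4.55-fold and TOP2A 4.18-fold, and MKI67 differed by 0.69 on the log2 scale. DNA repair genes had a median of 0.71 at percentile 98.9, with 7 of 22 higher and 1 lower. PARP1 rose 4.93-fold, EXO1 4.15-fold and BLM 3.68-fold, and ATM was 6.97-fold higher in its brightest probe set, with 1 of 4 probe sets lower. The gene that fell, RAD51C, read -1.03 on the log2 scale and was named after its value was seen. CDKN2A was higher by 5.69 on the same array. Without probe sets that can bind several transcripts, the DNA repair list lay at percentile 96.8.

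Interferon response, cytokine and immediate early genes were lower as groups. Of 18 interferon response genes, 12 fell and 2 rose, with a median of -1.36 at percentile 0.07. OAS3 read -3.59 on the log2 scale, a bound, ISG15 was 7.25-fold and ISG20 6.97-fold lower, while BST2, encoding tetherin, rose 11.9-fold and HERC5, named after its value was seen, read 2.13 on the log2 scale. Of 11 cytokine and NF-kB genes, 6 fell and 0 rose, with a median of -1.27 at percentile 0.17. The members that fell most encode NF-kB pathway proteins and the cytokine LIF: NFKBIA by 4.92-fold, NFKB2 by 4.66-fold, LIF by 3.43-fold and RELB by at least 2.73-fold. With no background the median was -0.57 and the list no longer stood apart. NFKBIA read -0.63 without probe sets that can bind several transcripts and RELB -0.59 with the 60th percentile as background, both short of 2-fold. Of 23 immediate early genes, 13 fell and 1 rose, with a median of -1.17 at percentile 0.03. EGR1 was at least 40.9-fold lower, ZFP36 22.8-fold lower and FOS at least 18.2-fold lower. SPRY2, named after its value was seen, rose by at least 3.29 on the log2 scale. Antigen presentation genes did not stand apart, at percentile 4.20, with 6 of 14 lower and 0 higher, among them TAPBP at 14.9-fold, HLA-DRB1 at 9.62-fold and HLA-E at 3.13-fold. TAP2 was 3.51-fold higher in its brightest probe set, with 1 of 3 lower. Reads of HLA-DRB1 cannot be told from those of its close relatives.

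Oxidative stress and xenobiotic defence genes stood lower, with 14 of 25 fallen, 2 risen and a median of -1.48, below all 10000 random lists. NQO1, a quinone reductase, fell 54.1-fold, with 3 of 3 probe sets lower. The aldo-keto reductases AKR1C2 and AKR1C1, whose near-identical sequences make them hard to tell apart, were at least 57.3-fold lower and 52.0-fold lower, respectively. AKR1C1 read -0.65, short of 2-fold, without probe sets that can bind several transcripts. GSTP1 moved the opposite way, as did SLC7A11 at 2.72 on the log2 scale, named after its value was seen. Without probe sets that can bind several transcripts this list had a median of -0.41 at percentile 9.72.

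The remaining pathway lists did not stand apart. Wnt and Notch genes were divided, with 10 of 22 higher and 6 lower at percentile 95.7, and WNT5A was at least 11.7-fold higher. Of 17 p53 targets 3 rose and 4 fell, at percentile 48.5. GDF15, a stress-induced cytokine, was at least 67.7-fold lower (-0.67 on the log2 scale, short of 2-fold, with the mean of all probe sets), CDKN1A, encoding p21, 15.0-fold, TP53I3 9.91-fold and TP53INP1 4.14-fold lower. CCNG1, SESN1 and GADD45A, named after their values were seen, read 1.77, 1.44 and 1.06 on the log2 scale. Hypoxia and glycolysis genes had 5 of 29 higher and 7 lower, at percentile 51.5, with FBP1, a gluconeogenic enzyme reported as a Snail target, at least 86.9-fold lower, PFKL 4.62-fold lower, and PDK1 9.40-fold and NDRG1 5.84-fold higher. HK2, VEGFA and ADM, named after their values were seen, read 2.10, 1.63 and 1.45 on the log2 scale. Cholesterol and fatty acid synthesis genes had 4 of 20 higher and 4 lower, at percentile 45.4. STARD4 and SC5D were 10.6-fold and 3.31-fold higher (SC5D 0.58 on the log2 scale, short of 2-fold, without probe sets that can bind several transcripts), and SREBF1 and LSS 6.97-fold and 4.28-fold lower. Named after their values were seen, HMGCS1 and ACACB read 1.30 and 1.03, and MVD and DHCR7 -1.70 and -1.38.

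Oxidative phosphorylation genes had 3 of 28 higher, NDUFB8, NDUFB3 and NDUFA9 at 2.39-fold, 2.23-fold and 2.07-fold (NDUFA9 0.96 on the log2 scale, short of 2-fold, as deposited), and 1 lower, COX6C at 2.33-fold, at percentile 95.7. Unfolded protein response genes had 6 of 22 higher and 2 lower, at percentile 89.5. Among them ASNS rose 6.26-fold and HSP90B1 5.34-fold. TRIB3 and PPP1R15A, the members that fell and were named after their values were seen, read -1.89 and -1.08. The probe sets of XBP1 and ATF3 disagreed, their brightest reading -2.77 and 2.18 on the log2 scale. Glycan synthesis genes had 2 of 27 higher and 10 lower, at percentile 6.89, and moved past the limit under 5 of 10 alternative settings. ST6GALNAC2 was at least 15.1-fold lower, GALNT6 10.3-fold and B4GALNT1 at least 6.57-fold lower, and B4GALT6 read 3.78 on the log2 scale with 1 of 4 probe sets lower. ST6GAL1 and GALNT1, which rose and were named after their values were seen, read at least 2.26 on the log2 scale and 2.8-fold. Apoptosis regulators had 3 of 24 higher, PMAIP1 the most at 27.0-fold, and 5 lower, at percentile 5.58. BIK was at least 22.7-fold, BID 4.38-fold and BCL2L1 4.19-fold lower. Named after their values were seen, BIRC2 and CYCS read 1.64 and 1.09, and CASP6 and BAD -1.56 and -1.10. Ribosomal protein genes lay at percentile 83.9 with a median of 0.21, and the largest differences in brightest probe sets were those of RPS28, RPS15, RPL19 and RPL3, at 0.63, 0.60, 0.59 and 0.52.

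Markers of other cell types were also measured. Of 6 leukocyte markers above background, 0 rose and 0 fell, and LAPTM5 and ITGAM read -0.82 and -0.39 on the log2 scale. CD8A and CD4, below background on the array labelled 6SA-Snail, had bounds of -0.92 and -0.79. Of 5 endothelial, fibroblast and red cell markers, 0 rose and 0 fell, and PECAM1, DCN and HBB read -0.95, -0.59 and -0.33, with a bound of -0.67 for COL3A1. These lists lay at percentiles 21.4 and 27.7. A further list of genes known from HEK293, an embryonic kidney line with neuronal features, was written after the largest differences had been seen but left those out. Of its 15 members above background, 9 rose and 1, SOX11, fell, with a median of 2.61, above all 10000 random lists. These rises were on the array on which the epithelial, luminal and oestrogen response genes fell. The 3' to 5' ratio, a sign of RNA integrity, was 1.60 and 2.30 for ACTB on the control vector array and the array labelled 6SA-Snail, and 1.26 and 1.11 for GAPDH.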

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

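Tests chosen only after the result was seen are those of scaling, RNA integrity, unchanged MCF7 cells, CDKN2A, MDA-MB-231 genes, leukocyte and vascular markers, and both tests of the spike-in controls; those of second probe sets, MTAP, the amplified regions and the HEK293 list were written down before their values were seen.

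Probe sets outside the named genes also differed between the arrays. Of 4498 probe sets with no gene symbol above background on at least 1 array, 687 were at least 2-fold higher and 489 at least 2-fold lower on the array labelled 6SA-Snail. Of 1184 with several symbols, 177 were higher and 214 lower. Changed probe sets made up 26.1% and 33.0% of these groups. Both shares are below the 35.9% of genes, which were counted by gene and under a stricter rule. These probe sets belong to none of the comparisons above, and the 687 and 177 read above the control vector array.

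The first pattern is the extent of the difference, 4808 genes of 13389, with SNAI1 itself not above background. The tests of technical causes reach only part of them. The lowest count under another scaling was 4698 genes. A much lower count was hardly possible, because the deposited medians differed by only 0.18 on the log2 scale. Differences of genes above background on both arrays had an SD of 1.27. A second probe set was above background in 2904 genes whose brightest one differed at least 2-fold. These genes were taken without the rule that probe sets move the same way. The second brightest moved the same way as the brightest in 86.6%, which argues against probe-level noise. Both probe sets read the same RNA and hybridisation, so this cannot reach technical differences between whole arrays or cultures. The highest 3' to 5' ratio was 2.30, under a limit of 3 from a test chosen after the result was seen. Of the leukocyte, vascular, fibroblast and red cell markers, 0 of 11 rose. Unchanged MCF7 cells can make up little of the culture, since the KRT19 and TFF1 signal that background allows is at most 0.155% of the control.

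The second pattern concerns where the cells labelled 6SA-Snail come from, and it bears on every difference between these arrays, the gene families described last included. If 6SA-Snail in MCF7 were the whole cause, CDKN2A and MTAP, both deleted in MCF7 by textbook knowledge, would stay low: MTAP met this outcome as written beforehand, with -0.49 in its brightest probe set, although 2 of its 4 probe sets above background were at least 2-fold higher and that probe set also read above background on the control vector array. The CDKN2A test was added after its value and that of MTAP were seen. CDKN2A was higher by 5.69 on the log2 scale in its brightest probe set and by at least 4.32 in the other above background. Lists of genes in regions amplified in MCF7, around BCAS3 and ZNF217, had medians of -1.52 and -1.56, at percentiles 0.01 and 0. In them 9 of 13 and 7 of 13 genes above background fell and 0 rose by at least 2-fold. MED13 (-0.25) and STAU1 (-0.15) hardly moved, and CSE1L read 0.93. The CDKN2A and amplicon values argue against that explanation. A candidate explanation is RNA from another line, through a mislabelled sample or an overgrown culture: the HEK293 list had a median of 2.61, with NEFL at least 31.0-fold and IGF2BP3 at least 26.6-fold higher, but 8 of its 19 genes were above background on the control vector array, 4 on neither array, and PAX2, LHX1, INA and PEG10 did not rise, while a list from the mesenchymal breast line MDA-MB-231 had a median of -1.31 at percentile 0.07. Another line with similar genes or an effect of Snail on top of a different origin stay open, and the cells' genotype was not analysed here. A clone selected from MCF7 would lack CDKN2A too, so the CDKN2A values argue against it as well. The brightest MTAP probe set, at -0.49, does not.

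The third pattern lies in the spike-in controls. The 12 poly-A control probe sets, of bacterial transcripts added before labelling, were 2.88-fold lower on the array labelled 6SA-Snail (median -1.53 on the log2 scale, SD 0.20), and the 9 hybridisation controls, added after labelling, were 1.36-fold lower (-0.45, SD 0.14). Scaling would move both alike, but the poly-A controls differed from the hybridisation controls by -1.08. Values in this paragraph are as deposited, on which scale ribosomal protein genes had a median of 0.02, rather than 0.21 after normalisation. They lay 0.47 above the hybridisation controls, as less control RNA added or more messenger RNA per amount of total RNA would give. These stay open, and no biological explanation was tested.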

How the results depend on the processing

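SNAI1 stayed below background on both arrays under the 7 alternatives that set a background. The count of 4808 genes became 7218 with no background and 2629 at a 3-fold threshold, and stayed within 1.5 times of it under the other 9. Genes lower numbered 4014 with no background, 4002 at a 1.5-fold threshold and 1497 at a 3-fold threshold, and genes higher 1132 at a 3-fold threshold. The share of changed genes that were higher was 44.6%, against 51.0% with values as deposited and 51.9% with centring. The epithelial, luminal, oestrogen response, Snail target, TGF-beta, interferon, immediate early and cell cycle lists kept their direction and stood apart under all 10 alternatives. Lists that no longer stood apart were basal markers (-0.81), oxidative stress (-0.41) and DNA repair (0.72) without probe sets that can bind several transcripts, and cytokines with no background (-0.57). Lists that newly stood apart were mesenchymal markers (0.77 with the mean of all probe sets, 0.81 with the 60th percentile as background, 0.66 with a pseudocount of 32), collagens (-0.88 with the mean of all probe sets), antigen presentation (-1.18 with that mean, -0.88 with no background), Wnt and Notch (1.01 with no background, 0.74 with the pseudocount), and glycan synthesis (-0.54 as deposited, -0.53 centred, -0.86 with the mean of all probe sets, -0.72 both with the 60th percentile as background and with no background). With 1 common background, added after seeing the data, mesenchymal markers (0.45) and antigen presentation (-0.70) stood apart. No list that stood apart changed sign, and no named gene past the 2-fold rule did, but 187 of 989 alternative values of named genes moved by more than 1 probe set SD. The mean of all probe sets gave -1.12 for ESR1 and -0.67 for GDF15, since dim probe sets enter it. Named genes that passed the 2-fold rule fell short of it in some alternatives: also LEF1 (0.79) and FN1 (-0.92) with that mean, NFKBIA (-0.63), AKR1C1 (-0.65), SC5D (0.58) and TGFB1 (0) without probe sets that can bind several transcripts, RELB (-0.59) with the 60th percentile as background, and NDUFA9 (0.96) and CD44 (-0.82) as deposited, and both also with centring and CD44 with the pseudocount. Probe set disagreement was 0.78 with no background. The cause of the other shifts was not tested. The endothelial, fibroblast and red cell list had under 3 members, and so no value, with the mean of all probe sets and without probe sets that can bind several transcripts. Genes at background on 1 array have only bounds, which move with the background chosen. With 1 array per group, no replicate can be left out. No paired analysis was possible because each group is 1 array without a replicate number.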

Other observations

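The gene families in this part were looked at after the largest differences had been seen, and 28 were examined in all, some of them overlapping. Each family's direction was the same with values as deposited and with centring, unless stated. The doubt about where the cells labelled 6SA-Snail come from holds for each of them. HOX genes, the transcription factors of body axis position, were higher on the array labelled 6SA-Snail. Of 25 above background, 20 rose and 1, HOXC13, fell, with a median log2 difference of 2.09, above all 10000 random lists. HOXD13 and HOXD10 were at least 31.0-fold and 29.3-fold higher, and HOXB2, HOXB3 and HOXB6 at least 18.6-fold, 16.4-fold and 15.9-fold higher. Splicing and RNA-binding genes of the HNRNP, SRSF and SNRP families were also higher, with 10 of 39 risen, 0 fallen and a median of 0.78, above all 10000 random lists, among them HNRNPA3 at 5.81-fold and SRSF11 at 3.28-fold. Kinesins had a median of 0.63 at percentile 99.8, with 12 of 33 higher and 3 lower, and KIF15 rising 6.54-fold. ZNF genes had a median of 0.09, above all 10000 random lists, with 78 of 363 higher and 44 lower.

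Several families were lower. Of 12 S100A calcium-binding protein genes 9 fell and 0 rose, with a median of -2.98, below all 10000 random lists. S100A16 fell 51.5-fold, S100A14 50.5-fold and S100A11 27.8-fold. Of 30 histone genes 16 fell and 0 rose (median -1.63), H2AJ by at least 144-fold and H2AC6 by 39.0-fold, though histone probe sets can share signal between near-identical genes. All 6 metallothionein genes above background fell (median -1.86, percentile 0.24), again with shared sequence between members. RAB GTPases had 19 of 51 lower and 3 higher (median -0.83), RAB25, an epithelial recycling GTPase, by at least 98.0-fold and RAB3D by 14.9-fold. Keratins had 7 of 12 lower (median -1.52), galectins 3 of 4 (median -5.10, LGALS3 at least 345-fold and LGALS1 at least 88.3-fold), annexins 4 of 9 (median -1.03), and serpins 6 of 11 (median -1.27), though SERPINF1 and SERPINE2 rose 16.0-fold and 14.5-fold. Solute carriers (-0.26, percentile 3.53), tetraspanins (-0.45, percentile 15.6) and ephrins with their receptors (-0.60, percentile 9.73) were inside the range of the random lists. Proteasome subunits (-0.27, percentile 2.37), claudins (-1.15, percentile 2.04) and TMEM genes (-0.33, percentile 1.51) lay just below it. Just above it, at 0.11 and percentile 98.0, lay genes with symbols of developmental transcription factor families (ZIC, SOX, PAX, LHX, DLX and a further family). Inside it were heat shock and DNAJ genes (0.16), NDUF genes (0.21), tubulins (-0.47), protocadherins (-0.57), MAGE genes (-1.13), IGF genes (-0.76), GATA genes (-0.13), and TET and DNMT genes (-0.37). Families were taken by their symbols. The IGF genes therefore include the RNA-binding protein genes IGF2BP1, IGF2BP2 and IGF2BP3, and the GATA genes include antisense RNAs such as GATA3-AS1. Likewise, the developmental transcription factor families include the antisense RNA PAX8-AS1, and the NDUF genes include NDUFB2-AS1. MAGE genes taken with the GAGE, SSX, PAGE, XAGE, BEX and TCEAL genes had a median of 0, which was -0.05 under both other scalings.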
